A study of Mus musculus with 20 samples.

How the data were processed

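Messenger RNA was measured in lung tissue of 20 Sprague Dawley rats, 5 in each of 4 groups (sham males, bleomycin males, sham females and bleomycin females). Per the labels' protocols, the animals came from a cohort matched on body weight, total lung RNA was extracted with TRIzol, RNA integrity numbers were at least 7.0, poly-A RNA was captured with a stranded TruSeq kit and amplified for 15 cycles, and paired-end reads of 150 bases were taken on a NovaSeq at a median yield of 7.9 gigabases per sample. Per the labels' protocols, adapters were trimmed with Cutadapt 1.10, quality was looked at with FastQC 0.10.1, reads were aligned to the rat genome with HISAT2 2.0, and genes were assembled and quantified with StringTie 1.3.4. The organism field of the labels says Mus musculus, but the stock, the design text, the aligned genome and the ENSRNOG gene identifiers are those of rat, so the samples were treated as rat. The miRNA libraries that the labels mention were not analysed here. The bleomycin dose, its route and the time to tissue collection are not in the labels.

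The deposited table gives 2 units per gene and sample, counts and FPKM (fragments per kilobase per M fragments), per the file headers. Per the labels, the authors made the FPKM values with StringTie and imported counts into DESeq2 and edgeR, calling genes at a log2 fold change of at least 1 with a false discovery rate under 0.05. How whole counts were made from the StringTie output, and whether strand was used in counting, is not stated in the labels or the headers. The labels name Ensembl 112 and Rnor 6.0 together as the reference, although these do not belong to 1 release, so coordinates are printed as the table gives them and the build stays uncertain. The table holds 23799 genes. The deposited counts pile up at multiples of 4 (7103 values of 4 against 3459 values of 3 and 2447 of 5), so that 1 read pair seems to add about 4 counts. Library totals ran from 68.6 to 87.5 M counts (M for mega), or about 17.2 to 21.9 M read pairs if 4 counts stand for 1 pair. The yield stated in the labels implies 26.33 M pairs. The limit that a zero allows was therefore set at 3 read pairs, 12 counts, over the 5 libraries of a group. Counting intervals (95%) and this limit cover counting error only, since reads without molecular identifiers are not independent molecules.

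Genes with FPKM of at least 0.5 in at least 5 samples were tested, which kept 15875 genes and left 7924 untested. The planned design assumed FPKM values and limma, and named edgeR for the case of counts. Because the table holds counts, edgeR 4.0.16 was run on them in R 4.3.3 (TMM scaling, quasi-likelihood test with robust estimation, 1 mean per group, all 20 libraries in 1 model). Its adjusted p-values are Benjamini-Hochberg values over the 15875 genes, two-sided, with a prior count of 0.125 for fold changes. A gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in either direction. Every adjusted p in the text is from this test unless another is named. All log2 fold changes are with n = 5 per group, and the value after ± is the standard error for a log2 fold change and the standard deviation (SD) for FPKM. The 6 contrasts were bleomycin against sham in males, in females and averaged over both, females against males in sham and in bleomycin animals, and the sex by treatment interaction, coded as the female response minus the male response.

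The 35 gene lists, the contrasts, the main test and the rule for naming genes were fixed before the data were examined. For each list the members that rose or fell at an adjusted p under 0.05 over all tested genes were counted, and again with the p-values adjusted over the list alone. Each list was compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Of 204 pairs of list and contrast, 69 passed with the preset correlation and 8 with the estimated one. Genes were named by these rules. Per contrast, the 6 largest rises and the 6 largest falls among called genes with a proper symbol and a mean FPKM of at least 1 in 1 of the compared groups were taken, then up to 4 members with the smallest p of each list described, and always the Y-linked genes and Xist, Blmh, Esr1 and Esr2. Some genes that these rules name are not reported here. No gene is found under the symbol Xist, so it was not analysed here. Symbols shared by more than 1 gene (145 symbols) make a gene uncertain, and so do near-identical copies, among them the RT1 genes, the alpha globin genes and Ddx3 on the Y chromosome.

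Alternatives were no filter, a stricter filter (FPKM of at least 2), library totals or upper quartile factors in place of TMM, edgeR without robust estimation, only the groups compared, the replicate number as a block, limma on log2(FPKM + 0.1) and after quantile normalization, limma-voom with sample weights, DESeq2 1.42.0, and each library left out in turn. Alternatives chosen after seeing the data were counts divided by 4, protein-coding genes only, 1 spread weight per group, the mitochondrial percent of each library as a covariate, and the removal of 5 libraries with transcripts of neighbouring organs. Limma on log2(FPKM + 1), the test assumed before the table was known to hold counts, was added as an alternative once it was. The scripts were tested on simulated data drawn from the libraries' means with added changes. Only well-counted genes were changed, and 1 spread per gene served all groups. Recovery may thus be lower for low genes and in groups with more spread. The counts of false calls hold for equal spread only. Bleomycin males were more spread than the other groups, so false calls from unequal spread were not measured. The first shares use an adjusted p under 0.05 alone. For bleomycin against sham in males, 38.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, with 5 false calls among 15675 unchanged genes. With the fold minimum as well, 0 of 67, 29 of 67 and 61 of 66 were recovered. For the interaction the shares were 10.4%, 53.7% and 87.9%, with 8 false calls. With the fold minimum they were 1 of 67, 26 of 67 and 58 of 66. No 2 libraries of a group were copies of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.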

Results

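Lung RNA of 20 Sprague Dawley rats, an outbred laboratory stock, was sequenced after sham treatment or after acute lung injury by bleomycin, a glycopeptide that breaks DNA strands. There were 5 sham males, 5 bleomycin males, 5 sham females and 5 bleomycin females, each library from a separate animal, and the series title names the sex difference in the injured lung as its subject. Mean library totals were 79.9 ± 6.84 M counts in sham males, 78.5 ± 5.27 M in bleomycin males, 81.9 ± 4.11 M in sham females and 82.7 ± 6.70 M in bleomycin females (SD, n = 5). The first principal component held 30.5% of the variance and separated all 10 bleomycin libraries from all 10 sham libraries. The second held 14.2% and averaged −22.4 ± 38.9 in bleomycin males and 39.1 ± 9.61 in bleomycin females, with bleomycin male 4 at 34.3, among the females. Bleomycin males were also the most spread group, with a median SD of log2 CPM of 0.376 per gene against 0.212 in sham males, 0.165 in sham females and 0.218 in bleomycin females.

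**Figure D1:**
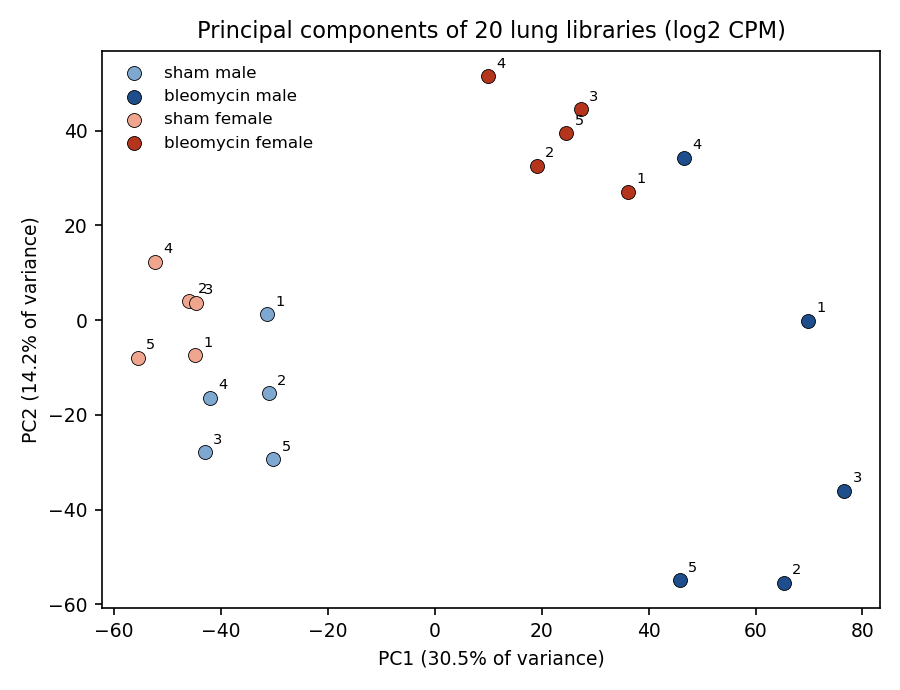
First against second principal component of log2 CPM for the 20 libraries, numbered by replicate. The axes hold 30.5% and 14.2% of the variance, sham libraries lie at the left, and bleomycin male 4 lies at 34.3 on the vertical axis, near the bleomycin females.

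The libraries differed in other ways that bear on the comparisons. Mitochondrial transcripts took 6.46 ± 1.23% of counts in sham males, 7.63 ± 1.97% in bleomycin males, 6.58 ± 0.706% in sham females and 4.94 ± 0.443% in bleomycin females (SD, n = 5). Transcripts of neighbouring organs were present at an FPKM of 50 or more in 5 libraries. Alb, the liver's main secreted protein, stood at 52.3 FPKM in sham male 3, 333 in sham male 5, 63.2 in bleomycin male 2, 97.0 in bleomycin male 5 and 61.4 in sham female 1. Sham male 3 also held skeletal muscle actin (Acta1) at 172 FPKM, and bleomycin male 5 held the fat cell gene Adipoq at 75.02 and the atrial gene Myl7 at 59.4. Of the Y-linked genes, Kdm5d (ENSRNOG00000060496, Y, 530401 to 624018 as the table gives it) averaged 6.72 ± 0.746 FPKM in sham males and 6.90 ± 2.15 in bleomycin males, and Eif2s3y 13.5 ± 1.57 and 18.6 ± 2.40. Both had no counts in the 5 sham females, and reached 0.0192 ± 0.0267 and 0.0125 ± 0.0280 FPKM in bleomycin females, in accord with the labelled sex of all 20 libraries. Esr1 and Esr2, the estrogen receptors, lay below the expression filter and were not tested.

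In males, bleomycin raised genes of matrix, cell division and macrophages and lowered genes of alveolar type 1 cells, endothelium and red cells. The fibronectin gene Fn1 went from 78.7 ± 12.98 to 339 ± 57.8 FPKM (SD, n = 5), and the macrophage complement gene C1qa from 8.83 ± 1.58 to 129 ± 48.9. The type 1 cell gene Rtkn2 went from 27.3 ± 6.53 to 4.81 ± 2.53 FPKM, the vascular growth factor receptor gene Kdr from 52.0 ± 15.3 to 15.7 ± 6.12, and the beta globin gene Hbb from 720 ± 186 to 49.3 ± 40.1. This comparison asked which transcripts differed between injured and sham lungs of males. Of 15875 genes tested, 2014 were called, 1233 higher and 781 lower with bleomycin, and 6645 had an adjusted p under 0.05. Limma on log2(FPKM + 1), a scale that understates changes of low genes, called 1029.

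Genes of the extracellular matrix were among those that rose in males. Of 24 tested members of the fibrillar matrix and fibroblast list, 17 rose and none fell at an adjusted p under 0.05 over all genes (17 and none adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 1.4e-10, but adjusted p = 0.284 with an estimated correlation). Fn1 rose by 2.09 ± 0.163 on the log2 scale (adjusted p = 2.1e-07), Cthrc1, a secreted protein of activated fibroblasts, by 2.89 ± 0.247 (4.5e-07), Thbs2 by 3.62 ± 0.369 (1.6e-06) and the fibroblast protease Fap by 3.85 ± 0.482 (9.0e-06). In the myofibroblast and smooth muscle list 7 of 10 rose and none fell (7 adjusted over the list alone; median 1.23, camera adjusted p = 0.00013, adjusted p = 0.284 with an estimated correlation). Desmin, Des, rose by 2.13 ± 0.252 and smooth muscle actin, Acta2, by 1.52 ± 0.256. Of 15 TGF-beta signalling and target genes 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0042, adjusted p = 0.284 with an estimated correlation). Of 16 matrix proteases and inhibitors 11 rose and 1 fell, with and without adjustment over the list alone (camera adjusted p = 0.00019, adjusted p = 0.284 with an estimated correlation). The inhibitor Timp1 went from 23.2 ± 3.52 to 225 ± 119 FPKM.

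Genes of cell division and of immune cells were the other rising groups in males. Of 26 cell cycle and proliferation genes 25 rose and none fell (25 adjusted over the list alone; median 1.70, camera adjusted p = 9.0e-24, adjusted p = 0.284 with an estimated correlation). The survivin gene Birc5 rose by 2.59 ± 0.2501 and the mitotic kinase gene Plk1 by 1.84 ± 0.188, from 3.22 ± 0.581 to 11.6 ± 2.81 FPKM. Of 21 macrophage and monocyte genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 1.24, camera adjusted p = 5.8e-07, adjusted p = 0.284 with an estimated correlation). C1qa rose by 3.83 ± 0.305 and the scavenger receptor Cd163 by 4.22 ± 0.473. Of 26 inflammatory cytokines and chemokines 16 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.00016, adjusted p = 0.284 with an estimated correlation). The interferon-induced chemokine Cxcl10 rose by 3.15 ± 0.381 and the monocyte attractant Ccl2 by 3.66 ± 0.524. Antigen presentation genes of MHC class II rose in 6 of 8 cases and fell in none (7 adjusted over the list alone; median 1.04, camera adjusted p = 0.0024, adjusted p = 0.364 with an estimated correlation). RT1-Db1 went from 11.3 ± 0.675 to 28.2 ± 11.5 FPKM and RT1-DMa rose by 1.53 ± 0.228. The DNA damage gene Bax, a p53 target that promotes cell death, rose by 1.31 ± 0.147 (adjusted p = 3.4e-06), within a p53 list of 26 genes of which 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.047, adjusted p = 0.284 with an estimated correlation). That list's call was lost in 15 of 38 settings, 6 of them without 1 library (sham male 5, bleomycin male 1, 2 or 4, sham female 1 or 2), with adjusted p = 0.075 at most, without bleomycin male 2.

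Genes of alveolar type 1 and type 2 cells, endothelium and red cells mostly fell or stayed in males. None of 12 alveolar type 1 cell genes rose and 8 fell (10 adjusted over the list alone; median −1.31, camera adjusted p = 5.8e-07, adjusted p = 0.284 with an estimated correlation). Rtkn2 fell by 2.54 ± 0.287 on the log2 scale (adjusted p = 3.6e-06) and the caveolin gene Cav1 by 1.48 ± 0.187 (9.6e-06). Of 18 endothelial cell genes 11 fell and 1 rose, with and without adjustment over the list alone (median −1.16, camera adjusted p = 4.3e-05, adjusted p = 0.364 with an estimated correlation). Kdr stood at −1.74 ± 0.234 and the angiopoietin receptor Tek at −1.23 ± 0.166. Of 13 alveolar type 2 cell genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.71 with an estimated correlation). The surfactant gene Sftpc went from 7105 ± 655 to 3176 ± 1646 FPKM. That list's call ended without bleomycin male 2 (adjusted p = 0.078). Of 9 erythroid and blood genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; median −2.13, camera adjusted p = 0.0042, adjusted p = 0.364 with an estimated correlation). Hbb stood at −3.85 ± 0.532 and the heme synthesis gene Alas2 at −3.77 ± 0.611. Without the 5 libraries with transcripts of neighbouring organs the type 2 and erythroid lists had adjusted p = 0.35 and 0.056.

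Genes with the largest changes in males were mostly near silent in 1 group. The intestinal-type membrane gene Ms4a12 and the protease inhibitor gene Wfdc18 had no counts in the 5 sham males and were at least 58.9-fold and 40.5-fold higher with bleomycin. Bleomycin male 2 held 392 of the 477 Wfdc18 counts, and without it the bound is 8.83-fold. Fgf23, a hormone of phosphate balance, had 6 counts over the sham males and 3480 over the bleomycin males, a ratio of 591 (95% counting interval 122 to 3663). Trh, the thyrotropin-releasing hormone gene, rose by 9.01 ± 1.34 on the log2 scale (adjusted p = 4.6e-05), the lectin gene Reg3b by 6.37 ± 1.48 (0.0031) and the Fc receptor-like gene Fcrl2 by 5.77 ± 0.7502 (1.3e-05). The largest falls were those of the fatty acid hydroxylase gene Cyp4a8 (−4.41 ± 1.16, adjusted p = 0.0052), Sirpb3 (−4.24 ± 0.464, 2.8e-06), Lgals5 (−3.88 ± 0.703, 0.00028), Hbb, Alas2 and the globin gene Hba-a3 (−3.77 ± 0.566, 5.1e-05). Blmh, the hydrolase that inactivates bleomycin, averaged 17.2 ± 1.38 FPKM in sham and 21.3 ± 3.85 in bleomycin males (log2 fold change 0.29 ± 0.121, adjusted p = 0.062).

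**Figure D2:**
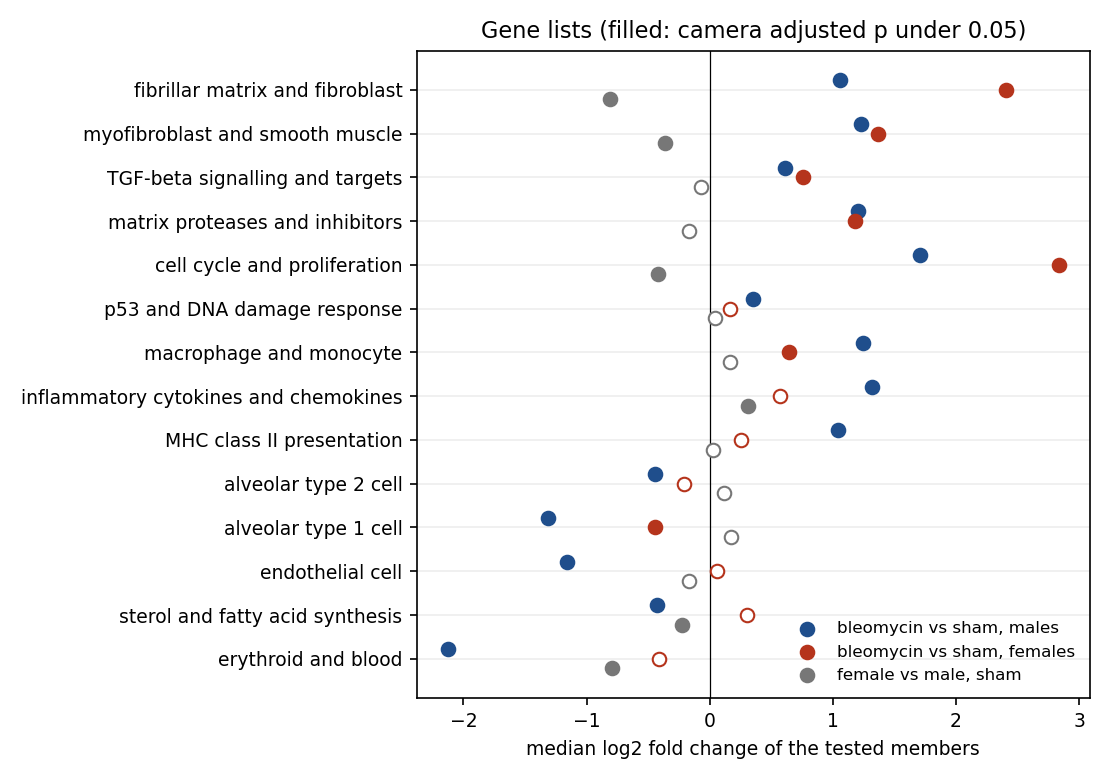
Median log2 fold change of the tested members of 14 gene lists for bleomycin against sham in males and in females and for sham females against sham males; filled points have a camera adjusted p under 0.05 with the preset correlation. The matrix list stands at 1.05 in males, 2.41 in females and −0.81 between the sham groups.

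In females, bleomycin raised matrix and cell division genes, while endothelial genes moved both ways and no gene of the MHC class II list passed the threshold. Fn1 went from 35.8 ± 5.05 to 325 ± 31.2 FPKM (SD, n = 5), the collagen gene Col1a1 from 31.0 ± 5.95 to 334 ± 66.9, and Plk1 from 1.85 ± 0.241 to 14.6 ± 2.28. C1qa went from 8.54 ± 1.80 to 38.0 ± 14.3 FPKM, and Rtkn2 from 34.6 ± 4.00 to 15.5 ± 2.37. The question was the same as in males. Of 15875 genes 1112 were called, 867 higher and 245 lower, and 3431 had an adjusted p under 0.05. Limma on log2(FPKM + 1) called 610, and edgeR with the mitochondrial percent as a covariate called 915.

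The fibrillar matrix and fibroblast list rose in 22 of 24 genes and fell in none, with and without adjustment over the list alone (median 2.41, camera adjusted p = 4.1e-45, and adjusted p = 0.0012 with an estimated correlation). Fn1 rose by 3.16 ± 0.170 on the log2 scale (adjusted p = 1.6e-09), the collagen cross-linking gene Loxl2 by 2.57 ± 0.172 (9.2e-09), Col1a1 by 3.41 ± 0.234 (1.3e-08) and the microfibril gene Fbn1 by 2.42 ± 0.176 (1.8e-08). All but 1 of the 26 cell cycle and proliferation genes rose, 25 with and without adjustment over the list alone (median 2.84, camera adjusted p = 2.1e-77, and adjusted p = 0.0012 with an estimated correlation). Plk1 rose by 2.95 ± 0.196, the topoisomerase gene Top2a by 3.09 ± 0.219 and Mki67, a marker of cycling cells, by 2.70 ± 0.195. Of 15 TGF-beta signalling and target genes 9 rose and none fell (11 adjusted over the list alone; camera adjusted p = 8.4e-09, and adjusted p = 0.013 with an estimated correlation). The myofibroblast and smooth muscle list rose in 8 of 10 genes (9 adjusted over the list alone; camera adjusted p = 2.8e-10, adjusted p = 0.075 with an estimated correlation). The gamma actin gene Actg2 rose by 3.04 ± 0.287. Of 16 matrix proteases and inhibitors 10 rose and none fell (11 adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.2 with an estimated correlation).

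Inflammatory and lung cell lists gave mixed results in females. Of 21 macrophage and monocyte genes 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.64, camera adjusted p = 0.014, adjusted p = 0.839 with an estimated correlation). C1qa rose by 2.13 ± 0.284 and Cd163 by 2.96 ± 0.448. Without bleomycin female 1 the list had an adjusted p of 0.081. Of 26 inflammatory cytokines and chemokines 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.144), Ccl2 by 3.65 ± 0.525 upward and the chemokine Ccl20 with a log2 fold change of −2.55 ± 0.459. The MHC class II list had a median of 0.25, a mean of 0.15 and a camera test pointing down (adjusted p = 0.992), so these differed in sign. None of its 8 genes passed, also not when adjusted over the list alone. Type 1 cell genes fell in 2 of 12 cases (2 adjusted over the list alone; median −0.45, camera adjusted p = 0.039, adjusted p = 0.839 with an estimated correlation), Rtkn2 at −1.19 ± 0.275 and Cav1 at −0.89 ± 0.184. Without bleomycin female 1 the list had an adjusted p of 0.066, and without bleomycin female 2 it had 0.057. Of 18 endothelial genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.776). The surface mucin gene Emcn stood at 1.01 ± 0.178, the lipase-binding gene Gpihbp1 at −1.47 ± 0.285 and Kdr, which averaged 56.9 ± 5.51 and 48.7 ± 10.3 FPKM, at −0.26 ± 0.227 (adjusted p = 0.46). Of 12 airway ciliated cell genes 2 fell (5 adjusted over the list alone; median −0.69, camera adjusted p = 0.0028, adjusted p = 0.839 with an estimated correlation). The tubulin-associated gene Tppp3 stood at −1.09 ± 0.2504.

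Fgf23 and Reg3b had no counts in the 5 sham females and were at least 134-fold and 100.2-fold higher in bleomycin females. Trh had 12 counts over the sham females and 1123 over the bleomycin females, a ratio of 92.7 (95% counting interval 31.4 to 453) that became 40.9 (13.7 to 203) without bleomycin female 1, which held 725 of them. The cytokine gene Il6 had 12 and 1114, a ratio of 92.0 (31.1 to 448). Fcrl2 rose by 6.18 ± 0.806 on the log2 scale (adjusted p = 1.4e-05) and the gap junction gene Gja3 by 5.85 ± 0.662 (2.5e-06). Large falls were those of Cyp2e1, a monooxygenase (−3.75 ± 0.682, adjusted p = 0.00052), the aldehyde dehydrogenase gene Aldh3a1 (−3.53 ± 0.700, 0.0011), the glycosyltransferase gene Galnt14 (−3.51 ± 0.488, 3.0e-05) and Cyp2b2 (−2.61 ± 0.423, 0.00017). The lens galectin gene Grifin had 432 counts in sham and 9 in bleomycin females, a ratio of 48.4 (14.7 to 456), or 12.9 (3.68 to 129) without sham female 2. Its adjusted p of 0.027 became 0.13 without sham female 2, 0.061 without bleomycin female 1, 0.057 without bleomycin female 2, 0.060 without bleomycin female 4 and 0.057 without bleomycin female 5. Blmh averaged 16.7 ± 0.627 FPKM in sham and 22.7 ± 1.30 in bleomycin females (log2 fold change 0.42 ± 0.121, adjusted p = 0.018).

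Averaged over both sexes, 1421 genes were called, 1012 higher and 409 lower, and limma on log2(FPKM + 1) called 662. All 26 cell cycle and proliferation genes rose, with and without adjustment over the list alone (median 2.34, camera adjusted p = 2.5e-54, and adjusted p = 0.0084 with an estimated correlation). Of 24 matrix genes 21 rose (21 adjusted over the list alone; median 1.59, camera adjusted p = 1.1e-28, and adjusted p = 0.0084 with an estimated correlation). Cyp4a8 (−2.98 ± 0.767), Cyp2b2 (−2.67 ± 0.300), Sirpb3 (−2.64 ± 0.305), Galnt14 (−2.62 ± 0.335), Cyp2e1 (−2.60 ± 0.458) and the growth factor gene Bmp15 (−2.56 ± 0.303) had the largest falls, and Fgf23, Reg3b, Trh, Wfdc18, Ms4a12 and Fcrl2 the largest rises.

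**Figure D3:**
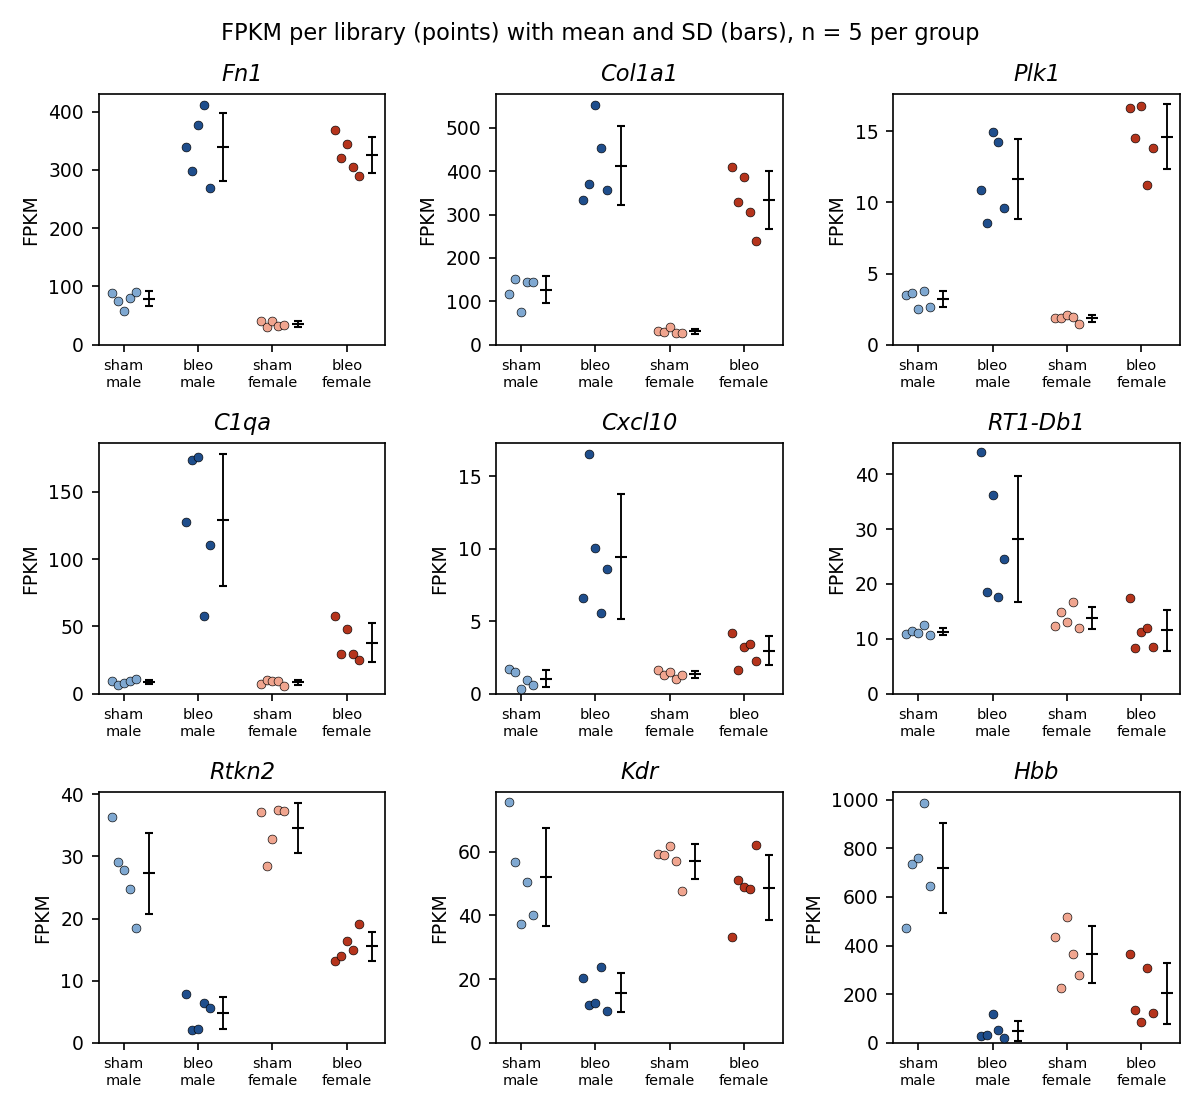
FPKM of 9 genes in each library (points) with the group mean and SD (bars), n = 5. Fn1 averages 78.7 in sham males and 35.8 in sham females, and Kdr averages 15.7 in bleomycin males and 48.7 in bleomycin females.

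The responses of males and females were compared gene by gene. Across 15875 genes the log2 fold changes correlated with Pearson r = 0.571 (jackknife standard error over libraries 0.088) and Spearman rho = 0.544 (0.111). These are correlations across genes, which are not independent replicates, and the 2 responses share no libraries. Without a filter on low values Pearson r was 0.275, and with DESeq2, also unfiltered, it was 0.281. Of 2436 genes called in either sex, 2191 (89.9%) had the same sign in both, and 2 were called in opposite directions. Both sexes had 580 called rises in common where independent lists would share 67.3, and 108 called falls where 12.1 would be shared. The median absolute log2 fold change of genes called in either sex was 1.32 in males and 1.00 in females. These genes were chosen by the same calls, 2014 in males and 1112 in females, which favours the male median. The medians therefore cannot show which sex responded more. Over all 15875 tested genes the SD of the log2 fold changes was 0.817 in males and 0.75004 in females.

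**Figure D4:**
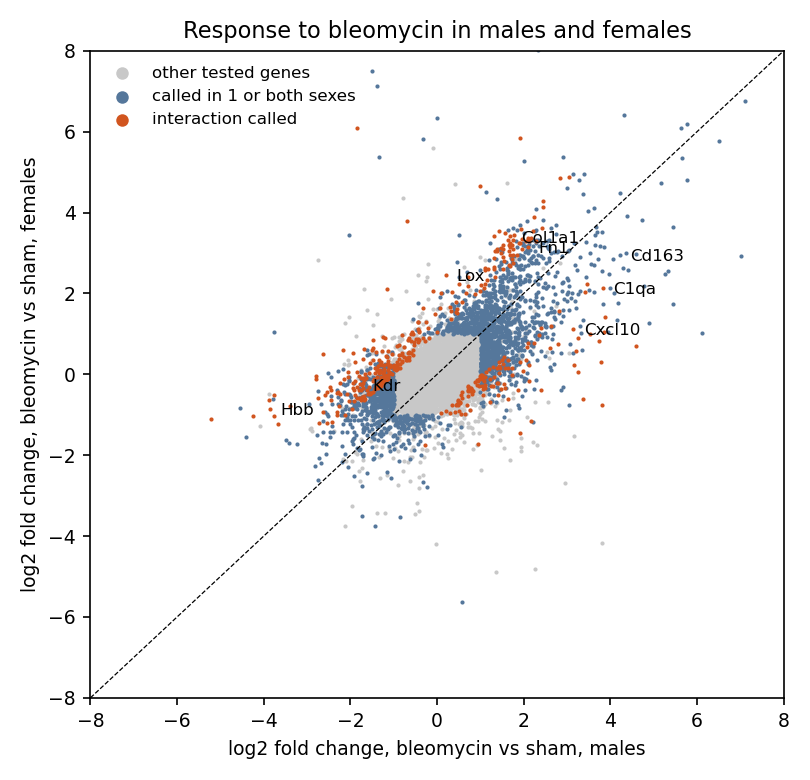
Log2 fold change with bleomycin in females against that in males for each tested gene, with the line of equal response dashed; 14 genes lie outside the axes, which end at 8. Genes called in 1 or both sexes and genes called for the interaction are coloured, and Col1a1 stands at 1.69 in males and 3.41 in females, Cxcl10 at 3.15 and 1.13.

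Sham females differed from sham males in Y-linked genes and in genes of the extracellular matrix, which were lower in females. Col1a1 averaged 126 ± 31.2 FPKM in sham males and 31.0 ± 5.95 in sham females (SD, n = 5). This comparison asked how uninjured lungs of the sexes differ. Of 15875 genes 48 were called, 7 higher and 41 lower in females, 83 had an adjusted p under 0.05, and the counts under other tools were 19 (limma on log2(FPKM + 1)), 170 (DESeq2) and 74 (only the 2 sham groups). Leaving out 1 library gave 22 to 65 calls, with fewer than 32 without sham male 4 (31), sham male 5 (24), sham female 1 (30), sham female 2 (27), sham female 3 (31), sham female 4 (22) or sham female 5 (23).

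The fibrillar matrix and fibroblast list was lower in sham females in 10 of 24 genes and higher in none (19 and 1 adjusted over the list alone; median −0.81, camera adjusted p = 3.7e-37, and adjusted p = 0.0048 with an estimated correlation). Col1a1 differed by −2.02 ± 0.221 on the log2 scale (adjusted p = 5.2e-05), Fbn1 by −1.33 ± 0.170 (0.00046), the collagen gene Col3a1 by −1.50 ± 0.194 (0.00047) and Loxl2 by −1.23 ± 0.165 (0.00073). No gene of the cell cycle list passed over all genes (7 lower adjusted over the list alone; median −0.42, camera adjusted p = 2.5e-10, adjusted p = 0.484 with an estimated correlation). The smooth muscle list was likewise lower as a set (3 lower adjusted over the list alone; median −0.37, camera adjusted p = 3.8e-05, adjusted p = 0.484 with an estimated correlation). The airway secretory, erythroid and sterol lists also passed camera with the preset correlation. Their medians over 38 settings were −1.31 to −0.531, −0.933 to −0.416 and −0.371 to −0.0328. The inflammatory cytokine list passed with positive medians (0.141 to 0.438). These 4 calls were lost in 6, 2, 4 and 2 settings. Of 8 X-linked genes with a Y partner or known escape from X inactivation 3 were higher in females (4 adjusted over the list alone; camera adjusted p = 3.7e-09, and adjusted p = 0.0048 with an estimated correlation). The translation factor gene Eif2s3 differed by 0.71 ± 0.0711, Pbdc1 by 0.63 ± 0.0958 and the histone demethylase gene Kdm6a by 0.78 ± 0.151, the last with an adjusted p of 0.019 that exceeded 0.05 without sham male 4 (0.052), sham male 5 (0.068), sham female 1 (0.055) or sham female 2 (0.066).

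Kdm5d, Eif2s3y, Ddx3 on the Y chromosome (ENSRNOG00000057231, 1116309 to 1135706) and Uty had no counts in sham females and were at least 1512-fold, 1411-fold, 1394-fold and 587-fold higher in sham males. The liver genes Cyp2c13 and Cyp3a2 were also lower in females, Cyp2c13 with no counts in females and at least 126-fold higher in males, and Cyp3a2 with 1966 counts against 4, a ratio of 504 (95% counting interval 90.1 to 19959). Without sham male 5, which held 1139 of the 1470 Cyp2c13 counts and 1535 of the Cyp3a2 counts, these became at least 35.9-fold and 140.2 (24.7 to 5600). Their adjusted p-values of 0.049 and 0.031 became 0.10 and 0.092 without sham male 5, the library with Alb at 333 FPKM, and each exceeded 0.05 without any 1 of the 5 sham females (0.12 and 0.11 at most). Cyp2c13 did so without 7 other libraries as well, at most 0.074 without bleomycin female 2. Higher in females were Galnt14 (2.19 ± 0.459, adjusted p = 0.031), the endothelial secreted protein gene Esm1 (1.78 ± 0.321, 0.012), Sgsm1 (1.58 ± 0.293, 0.015) and Tmem255b (1.03 ± 0.182, 0.011). Galnt14 had an adjusted p of 0.10 without sham male 2 and over 0.05 without sham male 5 or any 1 sham female, Esm1 had 0.15 without the 5 libraries with transcripts of neighbouring organs, and Sgsm1 had 0.053 without sham male 4, 0.060 without sham male 5 and 0.060 without sham female 4.

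**Figure D5:**
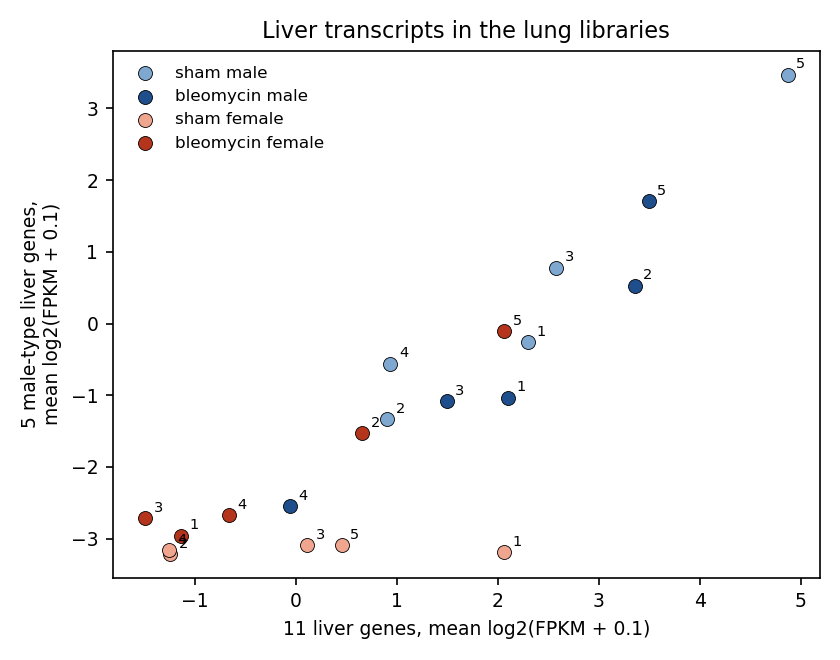
Mean log2(FPKM + 0.1) of 5 liver genes that are higher in male rats against that of 11 general liver genes in each library, numbered by replicate. Sham male 5 stands highest on both axes, and the 2 values rise together over the 10 male libraries (Pearson r = 0.946), with 0.970 in sham and 0.954 in bleomycin males.

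Among bleomycin animals, females had higher levels of endothelial and alveolar type 1 cell genes and lower levels of MHC class II and complement C1q genes than males. Kdr averaged 48.7 ± 10.3 FPKM in females and 15.7 ± 6.12 in males, Rtkn2 15.5 ± 2.37 and 4.81 ± 2.53, and C1qa 38.0 ± 14.3 and 129 ± 48.9 (SD, n = 5). The collagen cross-linking gene Lox averaged 82.8 ± 21.7 in females and 29.5 ± 20.4 in males. These groups also differed in mitochondrial share, 4.94 ± 0.443% in females and 7.63 ± 1.97% in males. Of 15875 genes 679 were called, 329 higher and 350 lower in females, but fewer in other fits. These gave 22 in the 2 bleomycin groups alone, 30 with the mitochondrial percent as a covariate, 245 without the 5 libraries with transcripts of neighbouring organs, and 307 with limma on log2(FPKM + 1). Of 103 named genes past an adjusted p of 0.05 in this comparison, 96 lost it in the 2 groups alone, 91 with the mitochondrial covariate and 58 without the 5 libraries. Over all settings run, the log2 difference stayed at 1.19 to 1.87 for Kdr, 1.46 to 1.93 for Rtkn2 and −1.96 to −1.55 for C1qa. Not all named genes held so, and Thrsp and Adipoq changed sign with the mitochondrial covariate. The count of calls was 436 without bleomycin male 2 and 1195 without bleomycin male 4.

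Of 18 endothelial cell genes 11 were higher in bleomycin females and none lower (12 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 6.8e-08, adjusted p = 0.331 with an estimated correlation). Kdr stood at 1.63 ± 0.233 (adjusted p = 0.0010) and Tek at 0.84 ± 0.164 (0.0037). Of 12 type 1 cell genes 8 were higher and none lower (9 adjusted over the list alone; median 0.96, camera adjusted p = 4.2e-08, adjusted p = 0.331 with an estimated correlation). Rtkn2 stood at 1.71 ± 0.279 (0.0016). None of the 8 MHC class II genes was higher and 6 were lower (7 adjusted over the list alone; median −1.02, camera adjusted p = 4.0e-06, adjusted p = 0.331 with an estimated correlation). RT1-Db1 stood at −1.28 ± 0.242 (0.0031). Of 21 macrophage genes 6 were lower (8 lower and 2 higher adjusted over the list alone; median −0.56, camera adjusted p = 0.00091, adjusted p = 0.747 with an estimated correlation). C1qa stood at −1.75 ± 0.280 (0.0016) and C1qb at −1.53 ± 0.252 (0.0016). Of 26 cell cycle genes 10 were higher (15 adjusted over the list alone; median 0.47, camera adjusted p = 2.6e-06, adjusted p = 0.747 with an estimated correlation). The replication genes Pcna and Mcm2 stood at 0.65 ± 0.135 and 0.59 ± 0.130. With the mitochondrial covariate this list had an adjusted p of 0.29. The matrix list, lower in sham females, had a median of 0.08 here with 2 genes higher and none lower (2 adjusted over the list alone; camera adjusted p = 0.786), Lox at 1.49 ± 0.332 (0.0068) and Col1a1 at −0.31 ± 0.213 (0.31).

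By the rule of size, Spock3 (2.61 ± 0.648, adjusted p = 0.011), Lgals5 (2.57 ± 0.670, 0.014), Sirpb3 (2.39 ± 0.433, 0.0025) and Acoxl (2.31 ± 0.436, 0.0030) were among the genes most raised in bleomycin females relative to males. Without the 5 libraries with transcripts of neighbouring organs Spock3 had an adjusted p of 0.077 and Lgals5 of 0.097. Gphn (2.76 ± 0.948, 0.046) and Rpp14 (2.34 ± 0.797, 0.045) were also among them, and each exceeded 0.05 without several single libraries, at most 0.15 without bleomycin female 3 for Gphn and 0.12 without bleomycin female 5 for Rpp14. Uty had no counts in bleomycin females and was at least 545-fold higher in males, and Eif2s3y (−10.44 ± 0.624), Ddx3 (−8.997 ± 0.927) and Kdm5d (−8.48 ± 0.733) followed. The fat cell genes Plin1 (−7.00 ± 2.38, adjusted p = 0.044) and Thrsp (−5.46 ± 1.75, 0.035) were lower in females, with adjusted p = 0.74 and 0.41 without bleomycin male 5, the library with Adipoq at 75.02 FPKM. Both also exceeded 0.05 without single other libraries, at most 0.091 (Plin1, without bleomycin female 2) and 0.079 (Thrsp, without bleomycin female 4). Plin1 averaged 10.5 ± 23.1 FPKM in bleomycin males, of which that library held 51.8.

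The interaction asked whether the response to bleomycin itself differed between the sexes. Some matrix, cell cycle and endothelial genes passed with a more positive response in females, and fewer macrophage, MHC class II and T cell genes with a more positive response in males. No list call of this contrast held with an estimated correlation (adjusted p of 0.395 or more). Vwf, the endothelial clotting factor gene, averaged 79.1 ± 6.08 and 50.03 ± 15.3 FPKM in sham and bleomycin males and 55.8 ± 2.09 and 82.4 ± 10.1 in sham and bleomycin females (SD, n = 5). Of 15875 genes 412 were called, 296 with the more positive response in females and 116 in males. In edgeR with the mitochondrial percent of the libraries as a covariate 0 genes were called (3016 genes had an unadjusted p under 0.05). Without the 5 libraries with transcripts of neighbouring organs 21 were called, 18 of them among the 412. DESeq2 called 824. Leaving out 1 library gave 173 (without bleomycin male 2) to 1143 calls (without bleomycin male 4). It also gave 265, 185 and 226 without sham male 1, 4 or 5, 195, 238, 218 and 197 without sham female 2, 3, 4 or 5, and 177, 208 and 184 without bleomycin female 2, 3 or 4.

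Of 24 matrix genes 10 had a more positive response in females and none in males (15 adjusted over the list alone; median 0.90, camera adjusted p = 7.4e-12, adjusted p = 0.395 with an estimated correlation). The difference was 1.70 ± 0.238 for Fbn1 (adjusted p = 0.0045), 1.47 ± 0.231 for Loxl2 (0.013), 1.72 ± 0.303 for Col1a1 (0.014) and 2.25 ± 0.467 for Lox (0.020). For Col1a1 the female to male difference was −2.02 in sham and −0.31 in bleomycin animals. Of 26 cell cycle genes 13 had a more positive response in females (19 adjusted over the list alone; median 1.01, camera adjusted p = 8.8e-14, adjusted p = 0.395 with an estimated correlation). Kif11, a spindle motor, stood at 1.69 ± 0.359, Top2a at 1.35 ± 0.287 and Nusap1 at 1.56 ± 0.340. Of 18 endothelial genes 5 did (13 adjusted over the list alone; median 0.97, camera adjusted p = 1.0e-08, adjusted p = 0.395 with an estimated correlation). Kdr stood at 1.48 ± 0.323, Vwf at 1.21 ± 0.251 and the junction cadherin Cdh5 at 1.35 ± 0.314. Of 17 sterol and fatty acid synthesis genes 2 did (8 adjusted over the list alone; median 0.69, camera adjusted p = 2.5e-05, adjusted p = 0.458 with an estimated correlation, and 0.069 without the 5 libraries).

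Of 21 macrophage genes 3 had a less positive response in females (4 adjusted over the list alone; median −0.71, camera adjusted p = 0.00011, adjusted p = 0.458 with an estimated correlation). C1qa stood at −1.70 ± 0.389 (adjusted p = 0.023). RT1-Db1 was the only MHC class II gene to pass over all genes, at −1.57 ± 0.340 (0.020), and 6 of 8 passed adjusted over the list alone (median −1.005, camera adjusted p = 0.00011, adjusted p = 0.41 with an estimated correlation). Of the T and NK cell genes 2 passed with a less positive response in females (5 adjusted over the list alone; median −0.84, camera adjusted p = 0.0021, adjusted p = 0.585 with an estimated correlation). With the mitochondrial covariate this list had an adjusted p of 0.055. Of 9 erythroid genes 3 had the more positive response in females (4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.462 with an estimated correlation). Hbb, at 2.99 ± 0.686, averaged 365 ± 117 and 203 ± 126 FPKM in sham and bleomycin females. That list had an adjusted p just over 0.05 without bleomycin male 4 and 0.064 without bleomycin female 4. Among single genes, Gja3 (3.94 ± 0.803, adjusted p = 0.019) and the collagen-binding integrin gene Itga2 (3.26 ± 0.612, 0.016) were among those leaning most toward females. The protease genes Capn8 (−4.58 ± 0.812, 0.014) and Prss30 (−3.20 ± 0.744, 0.024) leaned toward males. Each of these kept an adjusted p under 0.05 without any 1 library. With the mitochondrial percent as a covariate they exceeded it, as did all 53 genes named for this contrast. Without the 5 libraries with transcripts of neighbouring organs 49 of the 53 did.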

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

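The tests in this part were chosen after the results were seen, except those of unequal spread for the interaction and of a single library and of fibroblast number for the matrix genes. The group weights used for unequal spread were themselves added after the data were seen, and the test was written before its result. Genes called for a differing response included members of the matrix, cell division, endothelial and macrophage lists, with 10 of 24, 13 of 26, 5 of 18 and 3 of 21 at an adjusted p under 0.05, and 1 of 8 MHC class II genes. No interaction list call held with an estimated correlation (adjusted p of 0.395 or more). Of the genes named here, the tested difference in response (females minus males, log2) was positive for Gja3 (3.94), Sult1c3 (3.67), Alas2 (3.27), Itga2 (3.26), Lgals5 (3.25) and H19 (4.50), and negative for Ms4a12 (−6.78), Capn8 (−4.58), Cxcl6 (−3.98), Tmem202 (−3.48), Adig (−3.32) and Prss30 (−3.20). The call of H19 was lost in 27 of 36 settings, 16 of them leaving out 1 library, and its value was 2.88 without sham male 3 (adjusted p = 0.11) and 0.70 in limma on log2(FPKM + 1). The value for Ms4a12 is a fitted one against sham males without counts. Matrix and TGF-beta genes gave 1.70 for Fbn1, 1.47 for Loxl2, 1.72 for Col1a1, 2.25 for Lox, 1.57 for Ltbp2 and −0.99 for Tgfbi. Dividing cells gave 0.87 for Mcm2, 1.69 for Kif11, 1.35 for Top2a, 1.56 for Nusap1 and 1.04 for Lmnb1, and endothelial, lymphatic and vasoactive genes gave 1.21 for Vwf, 1.48 for Kdr, 1.35 for Cdh5, 2.11 for Ednrb, 0.88 for Flt4, 1.19 for Lyve1 and 1.12 for Ace.

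Immune genes gave −1.70 for C1qa, −2.47 for Trem2, −1.22 for C1qb, −2.02 for Cxcl10, −2.80 for Cxcl13 and −1.60 for Ccl4. They also gave −1.53 for Cd3d, −1.80 for Cd8b and −1.57 for RT1-Db1, and 1.47 for the mast cell receptor Kit. The complement gene Cfd gave −2.93. Bleomycin male 5 held the fat cell genes Adipoq at 75.02 and Plin1 at 51.8 FPKM. Fat in that library was not set apart from the values for Cfd and Adig. Damage response genes gave −0.85 for Bax, 1.69 for Tnfrsf10b, −0.73 for Aen and 0.85 for Perp. Epithelial and hypoxia genes gave 1.21 for Clic5, 1.34 for Rtkn2, −0.92 for Ndrg1 and −1.90 for Cldn4, sterol genes 1.58 for Hmgcs1 and 1.12 for Lss, and globin genes 2.99 for Hbb and 2.60 for Hba-a1. The adjusted p-values of these genes ran from 0.0045 (Fbn1) to 0.049 (Adig). Of the 53 genes, 32 exceeded an adjusted p of 0.05 without some single library, 49 without the 5 libraries with transcripts of neighbouring organs, and all 53 with the mitochondrial percent as a covariate.

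The 412 interaction calls are the first pattern weighed. Without the 5 libraries the called genes' differences had a median of 0.944 times the reported ones, and without any 1 library at least 0.932 times (lowest without bleomycin male 2). These ratios show that the sizes of the called genes' differences largely stayed. The genes were called with all 20 libraries, a choice that favours genes steady across them. The ratios therefore cannot exclude the 5 libraries or any 1 library as a cause of the calls. The number of calls fell to 21 without the 5 libraries and to 173 without bleomycin male 2. With 1 spread weight per group 543 genes were called, by limma-voom in place of edgeR. No limma-voom fit without weights was run. The count therefore cannot separate the tool from the weights, and unequal spread is left open. With the mitochondrial percent as a covariate the median ratio was 0.817 (quartiles 0.717 and 0.958), the median absolute difference went from 1.37 to 1.17 and its standard error from 0.340 to 0.389, and edgeR called 0 genes (3016 at an unadjusted p under 0.05). The bound for this test was set after its value was seen, and the share moved with the groups (7.63% in bleomycin males, 4.94% in bleomycin females), so a sex difference in the response and a difference in tissue state or RNA quality that the share tracks cannot be told apart. Of 60 splits 1 (the real one) called as many, real 412 and highest other 103, the smallest share that 60 splits can give. The splits regrouped sex within each treatment. They therefore also broke up plain sex differences, do not test the interaction alone and do not exclude a chance split of the animals.

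The lower matrix genes of sham females are the second pattern. Leaving out 1 sham library kept at least 0.917 of the list's median, and 17 fibroblast identity genes, none of them in the matrix list, had a median of −0.126 (13 lower in females), 0.156 of the matrix median. The lowest of the 17 was Ptn at −0.576, and 0 had an adjusted p under 0.05. The smooth muscle list reached 0.452 of the matrix median. These values argue against 1 library and more smooth muscle as the whole cause. They argue against more fibroblasts only so far as the 17 genes mark fibroblasts, which was not tested. The airway secretory list also had negative medians, −1.31 to −0.531 over the settings run. More airway wall is therefore left open. A more active growth programme in males, such as a difference in age or growth rate, may contribute and is left open. The 12 growth and imprinted genes had a median of −0.29, with 8 lower in females. Only 1 of them, H19, had an adjusted p under 0.05 (−6.18, adjusted p = 0.010). H19 was highest in sham male 3, at 29.1 FPKM.

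Liver transcripts of male type are the third pattern. Over the 10 male libraries the mean log2 of 5 male-type liver genes followed that of 11 liver genes with Pearson r = 0.946 (permutation p = 9e-05, adjusted p = 1e-04, the only relation tested, 100000 resamples; Spearman rho = 0.952, permutation p = 1e-04), with 0.850 without sham male 5 and bleomycin male 4, 0.970 in sham and 0.954 in bleomycin males. A candidate source of Cyp2c13 and Cyp3a2 in the male libraries is therefore liver RNA. The amount of liver RNA alone does not account for their lack in sham female 1. That library had Alb at 61.4 FPKM and no counts of either gene, with the female-type liver gene Cyp2c12 at 3.02 FPKM. In bleomycin female 5, Y-linked counts reached 0.184% of the male mean and liver genes 45.4%, a ratio of 0.00406, which argues against mixing with a male library of the series. Cyp2c12, a female-type liver gene, gave a ratio of 0 to the 1.30 FPKM that the sham females' ratio to Alb predicts there, so male liver carried over and a changed liver in the same animal cannot be told apart, from 1 library.

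Single libraries stood apart from the other 4 of their group in 13 of 132 groups tested (Dixon's ratio above 0.71). Alb and the fat gene Plin1 account for 5 of the 13. The genes tested were picked from those in the text, some already seen to be high in 1 library. The share therefore cannot be set against chance. Alb was 333 FPKM in sham male 5 (others 11.5 to 52.3), 61.4 in sham female 1 (0.364 to 11.3) and 25.6 in bleomycin female 5 (0.622 to 6.42). Cyp2e1 was 11.9 in sham female 5 (8.05 to 8.62) and 2.13 in bleomycin female 5 (0.180 to 0.690), and in sham females its highest library was not the one highest in Alb. Plin1 was 2.92 in sham male 4 (0 to 0.315) and 51.8 in bleomycin male 5 (0 to 0.449). The imprinted H19 was 29.1 in sham male 3 (0.0716 to 6.25), Lox 15.8 in sham male 3 (25.7 to 28.9), Scgb1a1 18407 in sham male 1 (33999 to 39152) and Muc5ac 1.36 in bleomycin female 1 (0.0487 to 0.372). Library totals were 74.9 M counts in sham female 2 (82.6 to 85.0). Eif2s3y was 0.0626 FPKM in bleomycin female 1 (0 in the others), and counts of 4 Y-linked genes summed to 76 in bleomycin female 1 and 20 in bleomycin female 5, against 0 in the sham females.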

How the results depend on the processing

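The mitochondrial covariate, the removal of the 5 libraries with transcripts of neighbouring organs, counts divided by 4, protein-coding genes only and group weights were chosen after seeing the data. Limma on log2(FPKM + 1), the test planned for FPKM values, became an alternative once the table was seen to hold counts. With an adjusted p alone the counts were 6645 (males), 3431 (females), 7181 (averaged), 83 (sexes in sham), 3239 (sexes in bleomycin) and 903 (interaction). Limma on log2(FPKM + 1), which shrinks low genes, called 1029, 610, 662, 19 and 307 in the first 5 of these, and 1035, 586, 652, 19 and 315 after quantile normalization. For the rest the cause was not tested. Between the sham groups voom with sample weights called 134, with group weights 109, DESeq2 170 and the 2 groups alone 74. Between the bleomycin groups the 2 groups alone gave 22 (21 of them among the 679), the mitochondrial covariate 30 (23 of them) and the removal of 5 libraries 245 (197 of them). For the interaction voom with sample weights gave 1155, DESeq2 824, the removal of 5 libraries 21 and the mitochondrial covariate 0 (edgeR, 3016 at an unadjusted p under 0.05). Agreement of the sexes without a filter was r = 0.275 and rho = 0.370, and 0.281 and 0.377 with DESeq2. Of 69 gene list calls 8 passed with an estimated correlation. Log2 differences reversed for Kdm5d averaged over the sexes after quantile normalization (−0.00215) and, with the mitochondrial covariate, for Thrsp (0.63) and Adipoq (0.18) between the bleomycin groups.

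Leaving out 1 library gave 1879 to 2281 calls in males, 997 to 1143 in females, 1346 to 1492 averaged, 22 to 65 between the sham groups, 436 (without bleomycin male 2) to 1195 (without bleomycin male 4) between the bleomycin groups and 173 to 1143 (without bleomycin male 4) for the interaction, r from 0.513 to 0.605, rho from 0.474 to 0.583, and 69 to 74 list calls. Interaction counts fell below 275 without sham male 1 (265), 4 (185) or 5 (226), bleomycin male 2 (173), sham female 2 (195), 3 (238), 4 (218) or 5 (197), or bleomycin female 2 (177), 3 (208) or 4 (184). The replicate number as a block gave 2036, 1100, 1424, 47, 662 and 472 calls, and equal numbers do not pair animals. For 547 named gene results, 18576 of 19984 comparisons kept direction and side of the threshold, 1395 lost the threshold, 10 gained it and 3 reversed. For the 69 lists 2420 of 2596 did and 176 lost it. The averaged and interaction contrasts need all 4 groups and had no fit with only the groups compared. Depth of about 17.2 to 21.9 M pairs limits folds against a group without counts to lower bounds, such as at least 58.9-fold for Ms4a12 in males. Esr1 was left out by the FPKM filter.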

Other observations

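The tests of splits and of gene biotypes in this part were chosen after the results were seen. Single genes of stress, airway and type 2 immunity lists moved with bleomycin, while the stress and airway lists as sets went both ways. Of 14 oxidative stress genes 5 rose and 4 fell in males and 3 rose and 3 fell in females (camera adjusted p = 0.713 and 0.769), and of 9 airway secretory genes 1 rose and 2 fell in males and 2 rose and 2 fell in females (0.193 and 0.586). Adjusted over the list alone, 4 airway genes fell in males and 4 stress genes in females, and the other counts were as given. The metal-binding gene Mt2A rose by 3.63 ± 0.479 in males and 2.70 ± 0.463 in females on the log2 scale, and Retnla, a gene of alternatively activated macrophages, by 3.98 ± 0.550 and 2.15 ± 0.508. The club cell secretoglobin Scgb1a1 changed by −1.87 ± 0.359 and −1.50 ± 0.355, from 33182 ± 8473 to 9121 ± 4850 FPKM in males and from 32612 ± 5343 to 11830 ± 2411 in females (SD, n = 5).

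Clock genes moved both ways. Npas2 changed by −1.26 ± 0.239 in males and −1.04 ± 0.238 in females, Bmal1 by −0.72 ± 0.218 and −1.09 ± 0.219, and the repressor Ciart by 1.35 ± 0.445 and 2.54 ± 0.472. Of 13 clock genes 4 rose and 4 fell in males (camera adjusted p = 0.592) and 4 rose and 3 fell in females (0.767), counts that were the same adjusted over the list alone. The hour of tissue collection is not in the labels. Small nucleolar RNAs made up 54 of the 1233 rises in males out of 173 tested (Fisher's exact test, adjusted p = 2.4e-18) and 10 of the 867 rises in females (adjusted p = 1). None of the 173 was among the 412 interaction calls, so a difference between the sexes is not shown. Fisher's test treats genes as independent and measures no spread between animals. The libraries were captured by poly-A. Bleomycin males 1, 2 and 5 had the most genes above 0 (20186, 20281 and 20424, others 19569 at most) and the highest mitochondrial shares. A difference in library make-up was not set apart from a rise of these RNAs.

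Other splits of the animals were fitted for each comparison. In each, 1 of 60 splits (the real one) called as many genes, the smallest share that 60 splits can give. The share is not adjusted over the 6 comparisons, so a chance split is made less likely but is not excluded. The real count and the highest other were 2014 and 673 in males, 1112 and 0 in females, 1421 and 455 averaged over the sexes, 48 and 1 between the sham groups, 679 and 601 between the bleomycin groups, and 412 and 103 for the interaction. For the bleomycin groups the margin is small, and 8 of the other splits called at least 1 gene.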
